A study of Mus musculus with 30 samples.

How the data were processed

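RNA was taken from pulverised brains of wild-type mice and mice labelled Csa-/- with TRIzol, and poly(A) RNA was made into libraries with a SOLiD Total RNA-Seq kit and sequenced on an AB SOLiD instrument, per the labels' protocols. The labels state that each sample was sequenced 5 times, and give paired reads of 75 bases. Trimmomatic 0.3.9, HISAT2 2.2.1, SAMtools and Subread 2.0.1 and the genome build mm10 are named there, without the role or the settings of each tool. The gene annotation was not given in the sources used here. Strain, sex and number of animals were not stated either.

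The deposited table held raw counts, as whole numbers for 25239 genes in 30 columns, and the authors made these counts with the tools above, per the labels. A total of 3431 genes had no count in any column. Of the gene symbols, 24319 matched GENCODE M21 and 25037 matched RefSeq GRCm38.p6, and 4 were changed into dates. Mitochondrial genes were not analysed here, and 6 haemoglobin genes had no count in any column. Each column's name matched the title of 1 sample, and no column was left over. Coordinates are those of mm10 in GENCODE M21.

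The groups were taken from the labels, with 2 genotypes and 3 ages. Comparisons, tests, gene lists, alternatives and the rule for named genes were written before the data were examined. The replicate check was planned to decide whether the 5 columns of a group were repeat runs. It used the chi-square of the 5 counts of each gene with a mean of at least 10 counts, and edgeR's common dispersion. Columns were to be summed if the median ratio was under 2 or the coefficient of variation under 0.05. Both held in all 6 groups, so the test planned for 30 columns was replaced by the form planned for 6 libraries.

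The tested comparisons used edgeR 4.0.16 quasi-likelihood F-tests in R 4.3.3 on the 6 summed libraries. TMM scaling (factors 0.955 to 1.03) and filterByExpr, which left 16560 genes, came first. The model held age and genotype, with 2 residual degrees of freedom and 3 libraries per genotype or 2 per age. It assumed that the spread was the same at each age and in each genotype. The common biological coefficient of variation was 0.278, and the prior had 77.2 degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The interaction of age and genotype had no residual and was not tested. P-values and SE rest on a spread between libraries pooled mostly over genes, since the prior outweighs the 2 residual degrees of freedom of each gene. That residual holds any disagreement of the genotype difference between ages. Nothing in the labels says how many animals each library held.

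Comparisons of single libraries used the fold of TMM-scaled CPM with an exact 95% Clopper-Pearson interval of the counts, and no p-value. A gene was called when it had at least 5 CPM in the higher library and the interval lay beyond 1.5-fold. The intervals were tested on simulated data with a true fold of 1.5 and covered it in 95.5% of 16560 genes. In simulated data for the genotype test, 22.4% of genes changed 2-fold and 97.0% of genes changed 4-fold were called, with 4 false among 122 calls. For 24 months against 45 days, 13% and 84.8% were called, with 2 false among 99. Small changes were therefore often missed. The simulated counts were independent between genes, used only the trended dispersion and held no trend with gene length or GC content. Their share of false calls need not hold for these libraries.

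Gene lists, 46 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested. Beside it stood camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over lists. In comparisons of single libraries, the median log2 fold of a list was placed among 10000 random lists matched on mean expression (seed 1), as a description. Percentiles above 99.9 or at 0 mean that few or none of the random lists lay beyond.

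The named genes were Ercc8 in every comparison and the sex-linked genes once. For each tested comparison they were the 10 genes with the largest log2 fold change in each direction with an adjusted p under 0.05 and a mean of at least 5 CPM, skipping gene models known only by an identifier and pseudogenes. For each single-library comparison they were the 10 largest called in each direction. Up to 4 members of each list were added, with an adjusted p under 0.05 and no bound on CPM in tested comparisons, and past the same bounds in single-library ones. Only part of the genes the rule allows is named in the text, and some of its results are not reported here.

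Alternatives were DESeq2 size factors, library totals, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, leaving out the 10 genes with most counts, each library in turn, and 30 columns as replicates with and without a replicate block. Chosen after the data were seen were the removal of each library's spline trend with exonic length and GC content (98.6% of genes had both), thinning to the smallest total, and leaving out each run number.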

Results

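Messenger RNA was measured by RNA sequencing in the brains of mice labelled Csa-/- and of wild-type mice at 45 days, 12 months and 24 months of age. Csa is another name of Ercc8, whose product acts in transcription-coupled repair of DNA and is lost in one form of Cockayne syndrome. The design compares the genotypes at each of the 3 ages. The series title names inflammation, neuronal signalling, the extracellular matrix, and the PI3K-Akt and MAPK pathways as its subjects. The table held 30 columns, 5 for each of the 6 groups, and the labels gave every column the same batch. Column totals ran from 2659732 to 8394376 counts.

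The 5 columns of each group behaved as repeat sequencing runs of 1 library. The median chi-square per degree of freedom between runs lay between 0.955 and 1.05. Counting error alone gives a mean of 1 and a lower median, so the runs varied slightly more than counting error. A chi-square p under 0.05 was found in 8.61% to 13.1% of genes. Between 1 run of each genotype at the same age the median was 2.22 to 6.66. That ratio has 1 degree of freedom, where counting error gives a still lower median, so the 2 ranges are not on 1 scale. The coefficient of variation between runs was 0.0249 to 0.0324. The runs were therefore summed, which left 1 library per group. Library totals were 21155348, 19648751 and 28723453 counts in wild type at 45 days, 12 months and 24 months, and 14762512, 14598535 and 37712210 counts in the libraries labelled Csa-/-. Levels are in CPM, counts scaled to a common library size after TMM scaling, and a floor of 3 counts was 0.0796 to 0.206 CPM. Intervals and floors cover counting error only.

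Ercc8 (chromosome 13, 108158731 to 108195364, mm10) was not reduced in any library labelled Csa-/-. Its level was 13.5, 11.3 and 12.4 CPM in wild type at 45 days, 12 months and 24 months, and 13.9, 13.1 and 13.4 CPM in the libraries labelled Csa-/-. The fold between genotypes was 1.03 at 45 days (95% counting interval 0.854 to 1.23), 1.16 at 12 months (0.947 to 1.41) and 1.08 at 24 months (0.944 to 1.24). Across ages the log2 fold change of Ercc8 was 0.12 ± 0.32 (SE, 3 libraries per genotype, edgeR adjusted p = 1). Counts over the whole gene cannot show an altered or interrupted transcript, so the genotype labels were not verified by Ercc8. Directions are therefore given for the library labelled Csa-/-. Xist and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty gave the same pattern in all 6 libraries.

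Across the 3 ages, Sgk1 and several glial genes rose in the libraries labelled Csa-/-. Sgk1 encodes a kinase induced by glucocorticoids (chromosome 10, 21882184 to 21999903) and stood at 67.9, 105 and 91.3 CPM in wild type at 45 days, 12 months and 24 months against 396, 182 and 357 CPM (log2 fold change 1.77 ± 0.33, SE, 3 libraries per genotype, edgeR adjusted p = 0.000977). Serpina3n, a gene of reactive astrocytes, rose from 27.4, 18.5 and 22.3 CPM to 44.8, 82.3 and 70.0 CPM (1.51 ± 0.32, adjusted p = 0.00754). Gpnmb, a gene of activated microglia, rose from 0.665, 2.56 and 5.84 CPM to 1.41, 8.18 and 29.0 CPM (1.78 ± 0.38, adjusted p = 0.00769). The microglial genes Cst7 (2.78 ± 0.56, adjusted p = 0.00367) and Clec7a (1.85 ± 0.42, adjusted p = 0.0217) rose too. Hif3a, a hypoxia-pathway gene (1.64 ± 0.35, adjusted p = 0.00766), and Fmo2, a monooxygenase gene (1.83 ± 0.41, adjusted p = 0.0163), also rose. Each of these genes moved the same way at 3 of 3 ages, as did all 30 genes called. The test favours such genes, since disagreement between ages is its residual, so this is no added support. Among 12175 genes with a mean of at least 5 CPM, Sgk1 was the only gene higher beyond 1.5-fold at every age (5.83, 1.73 and 3.91-fold).

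The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 30 of 16560 genes between genotypes, 9 higher and 21 lower. An unadjusted p under 0.05 was found for 366 genes, 258 of them higher. Among the lower genes were the pseudogene Tmem181b-ps (-6.41 ± 0.42, adjusted p = 1.18e-21), which may share reads with related copies, and the testis genes Smcp, Akap4, Crisp2, Tnp2, Prm2, Ldhc, Mael and Gsg1. These 9 genes lay outside the rule for named genes and were chosen after their values were seen. The balance of directions depended on the 24-month libraries, with 60 higher and 5 lower without the wild-type one (9 of the 30 shared) and 60 higher and 8 lower without the one labelled Csa-/- (10 shared). It was 3 higher and 37 lower without wild type at 12 months. The calls of Sgk1 and the other genes that rose did not all hold when a library was left out. In this model the age term fits a lone library of an age exactly. Leaving out either library of an age thus removes that age from the genotype test and lowers the residual degrees of freedom. The paired omissions below are therefore nearly the same test, and a lost call does not show dependence on 1 library. Without the wild-type library at 45 days, 67 genes passed, and the adjusted p was 0.215 for Sgk1 and 0.453 for Hif3a. Without the one labelled Csa-/- at 45 days, 72 genes passed, and these values were 0.203 and 0.452. When the wild-type library at 12 months was left out, 40 genes passed, and the adjusted p was 0.139 for Gpnmb, 0.552 for Serpina3n, 0.367 for Cst7 and 0.880 for Clec7a. Without the 12-month library labelled Csa-/-, 54 genes passed, with 0.110, 0.519, 0.439 and 0.886 for the same genes in that order. Leaving out wild type at 24 months gave 65 genes, and the adjusted p was 0.618 for Fmo2 and 0.219 for Gpnmb. Without the 24-month library labelled Csa-/-, 68 genes passed, with 0.770 for Fmo2, 0.397 for Gpnmb and 0.0943 for Clec7a. Removing each library's trend with gene length and GC content, a step chosen after the data were seen, left 11 genes, among them Tmem181b-ps and Sgk1. Under it Gpnmb (1.80 ± 0.31, adjusted p = 0.0593), Cst7 (2.85 ± 0.52, 0.0917), Hif3a (1.69 ± 0.33, 0.145), Serpina3n (1.52 ± 0.30, 0.145), Fmo2 (1.74 ± 0.36, 0.186) and Clec7a (1.70 ± 0.49, 1) did not pass. Their log2 fold changes stayed near those before it, while the prior degrees of freedom of the fit fell from 77.2 to 11.8, which raises p at a given fold and spread. In DESeq2, Fmo2 (0.0731) and Clec7a (0.0913) did not pass. Over 16 settings the log2 fold change ranged from 1.38 to 2.26 for Sgk1, from 1.17 to 1.91 for Serpina3n and from 1.43 to 2.02 for Gpnmb.

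**Figure D1:**
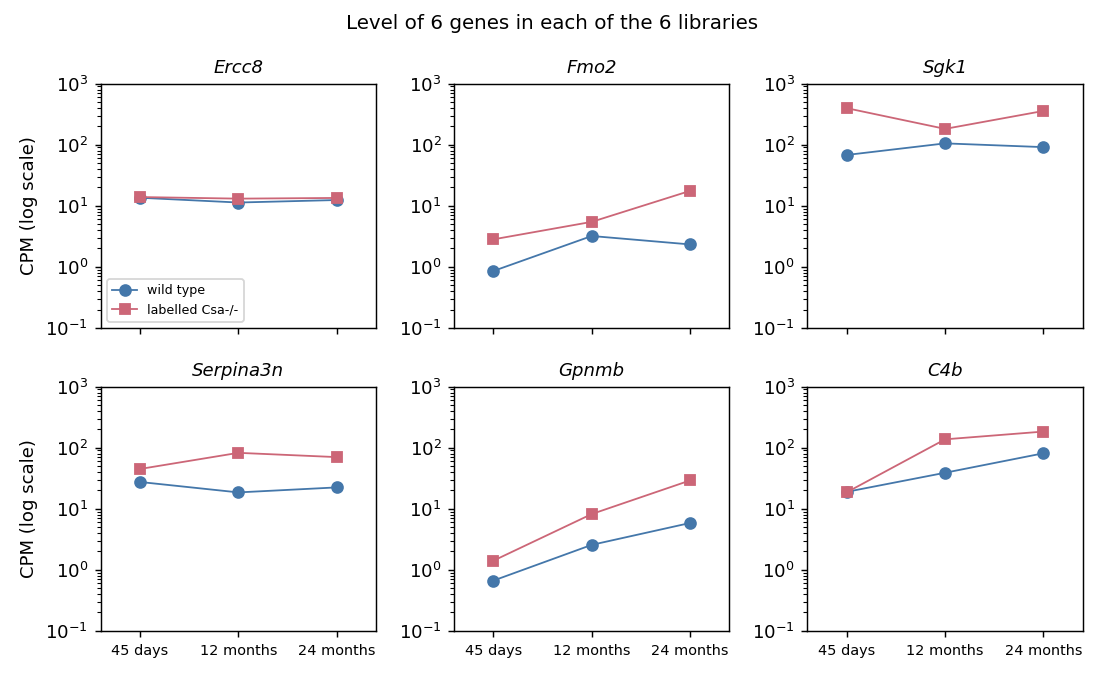
Level in CPM (log axis) of Ercc8, Fmo2, Sgk1, Serpina3n, Gpnmb and C4b at each age, with 1 library per point, wild type as circles and labelled Csa-/- as squares. Ercc8 stayed between 11.3 and 13.9 CPM in all 6 libraries, while Sgk1 stood at 67.9 to 105 CPM in wild type and 182 to 396 CPM in the libraries labelled Csa-/-.

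Genes of inflammation were higher as a group in the libraries labelled Csa-/-, and so were markers of several brain regions. The lists of the extracellular matrix, MAPK and PI3K-Akt were not called across ages. Of 31 inflammation genes, 30 were higher (median log2 fold change 0.54, camera adjusted p = 2.47e-18, adjusted p = 0.333 with an estimated correlation). Serpina3n alone of them passed over all genes tested, and 6 passed when adjusted over the list alone. Of 26 interferon-response genes, 24 were higher (median 0.48, camera adjusted p = 2.07e-12, adjusted p = 0.333 with an estimated correlation). None of these 26 passed in edgeR over all genes tested or adjusted over the list alone, with 10 at an unadjusted p under 0.05 and none passing in DESeq2 or limma-voom. The lists of reactive astrocytes (18 of 19 higher, median 0.44, camera adjusted p = 5.71e-07), activated microglia (13 of 16, median 0.30, 2.16e-08) and complement (11 of 12, median 0.54, 6.44e-06) were called higher too (all 3 with adjusted p = 0.571 with an estimated correlation). Adjusted over the list alone, 2, 6 and 1 of their genes passed. The immediate early genes (19 of 20, median 0.26, camera adjusted p = 0.000406, adjusted p = 0.572 with an estimated correlation) were called higher as well. The list of 16 genes of cell senescence, of which 11 were tested, had 10 higher (median 0.64, 1.68e-05, adjusted p = 0.438 with an estimated correlation). Choroid plexus markers were called lower (14 of 15, median -0.23, 0.00229, adjusted p = 0.593 with an estimated correlation). Regional markers moved in the same test. Those of cerebellum (15 of 16 higher, median 0.28, camera adjusted p = 7.43e-05, adjusted p = 0.438 with an estimated correlation), of thalamus and brainstem (13 of 17, 0.42, 0.000372, adjusted p = 0.571 with an estimated correlation) and of olfactory bulb (13 of 15, 0.26, 0.0217, adjusted p = 0.571 with an estimated correlation) were called higher. Those of striatum (14 of 15 lower, -0.18, 0.0212, adjusted p = 0.572 with an estimated correlation) and of ependymal cilia (10 of 14 lower, -0.41, 0.00266, adjusted p = 0.571 with an estimated correlation) were called lower. Pituitary markers were called higher (7 of 12, 0.14, 0.0198, adjusted p = 0.739 with an estimated correlation). Markers of cortex and hippocampus (13 of 17 lower, -0.12, 0.0490, adjusted p = 0.704 with an estimated correlation) and of mural cells and fibroblasts (11 of 18 lower, -0.07, 0.0467, adjusted p = 0.572 with an estimated correlation) were called lower.

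Extracellular matrix genes (19 of 47 higher, median -0.14, camera adjusted p = 0.0652), MAPK genes (21 of 43 higher, median 0.00, 0.937) and PI3K-Akt genes (21 of 43 higher, median -0.01, 0.771) were not called. In neuronal signalling, the glutamatergic list was called lower (21 of 28 lower, median -0.10, 0.0297, adjusted p = 0.645 with an estimated correlation). The GABAergic list (12 of 22 higher, median 0.02, 0.804) and the monoamine and acetylcholine list (16 of 26 higher, median 0.07, 0.270) were not called. The list of p53 and DNA damage response genes was called higher (16 of 20, median 0.12, camera adjusted p = 0.0288, adjusted p = 0.571 with an estimated correlation), as was that of the circadian clock (13 of 16, 0.32, 0.00402, adjusted p = 0.572 with an estimated correlation). Genes of nucleotide excision repair were not called (8 of 19 higher, median -0.04, 0.709), nor were 54 genes next to Ercc8 on chromosome 13 (36 higher, median 0.09, 0.830). In all, camera with a preset correlation of 0.01 called 20 of 41 lists tested. With a correlation estimated from these libraries, camera called none of the 41 (4 at an unadjusted p under 0.05), and fry called none (5 at an unadjusted p under 0.05).

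At 45 days, extracellular matrix genes were lower in the library labelled Csa-/-, with a median log2 fold of -0.65 over 47 genes, at percentile 0 of 10000 random lists matched on expression. Tnr (0.322-fold) and Hspg2 (0.343-fold), which encode large matrix proteins, were among 10 of them lower beyond 1.5-fold, and none was higher. Sgk1 was 5.83-fold higher (95% counting interval 5.51 to 6.19), and the neuropeptide gene Cartpt 5.79-fold higher. Genes of oxidative phosphorylation (median 0.49, percentile 100) and of ribosomal proteins (0.44, percentile 100) were higher, with Ndufa1 at 2.99-fold and Rpl37a at 3.48-fold. With each library's trend with gene length and GC content removed, the medians were -0.28 for extracellular matrix, 0.11 for oxidative phosphorylation and 0.18 for ribosomal proteins. Interferon-response genes (median 0.47, percentile 99.7, Rtp4 3.14-fold) and inflammation genes (0.37, percentile 98.5, B2m 2.53-fold) were higher. Choroid plexus markers (-0.63, percentile 0.01, Ttr 0.439-fold) and glutamatergic genes (-0.43, percentile 0.06) were lower. The PI3K-Akt list had a median of -0.23 (percentile 1.40), with Itgb8 at 0.211-fold against Sgk1, and the MAPK list one of -0.18 (percentile 12.2). Of 12500 genes at 5 CPM or more, 1648 differed beyond 1.5-fold, 981 higher and 667 lower. This comparison and the other 8 between single libraries compare those libraries, not the conditions, and have no replicate check.

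At 12 months, inflammation genes stood higher in the library labelled Csa-/- (median 0.84, percentile 100), with 9 beyond 1.5-fold and none lower. The iron-binding protein gene Lcn2 was 32.7-fold higher (95% counting interval 13.7 to 102), Serpina3n 4.45-fold and the antigen-presentation gene Cd74 3.46-fold. Microglial genes were higher in the activated list (0.59, percentile 100), with Itgax at 11.9-fold, Clec7a at 8.35-fold and Gpnmb at 3.20-fold, while P2ry12, a gene of resting microglia, stood at 0.507-fold. Complement genes (0.76, percentile 100, C3 4.82-fold and C4b 3.53-fold) and reactive astrocyte genes (0.71, percentile 100, Gfap 2.92-fold and Vim 2.75-fold) were higher. The regional markers differed as well. Thalamus and brainstem markers (1.24, percentile 100, Hoxb5 5.11-fold) and pituitary markers (3.13, percentile 100, Pomc 71.9-fold) were higher, and cortex and hippocampus markers were lower (-0.54, percentile 0, Mef2c 0.443-fold). With the length and GC trend removed, the medians were 0.72 for inflammation, 0.89 for reactive astrocytes and 0.62 for activated microglia. Extracellular matrix genes had a median of 0.22 (percentile 99.4), MAPK genes -0.17 (percentile 13.5) and PI3K-Akt genes -0.17 (percentile 6.74). Of 12394 genes, 719 differed beyond 1.5-fold, 460 higher and 259 lower. Scaled by library totals alone, the split was 575 higher and 160 lower.

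At 24 months, immediate early genes stood higher in the library labelled Csa-/- (median 0.76, percentile 100), with 11 beyond 1.5-fold and none lower, among them Apold1 (3.55-fold) and Dusp1 (3.20-fold). Reactive astrocyte genes (0.71, percentile 100, Osmr 4.00-fold and Serpina3n 3.13-fold) and inflammation genes (0.52, percentile 100, Tlr7 3.28-fold) were higher, as were Fmo2 (7.53-fold) and Gpnmb (4.97-fold). Interferon-response genes had a median of 0.46 (percentile 99.95). MAPK genes (0.49, percentile 100, Cacnb4 2.24-fold and Nf1 2.15-fold) and PI3K-Akt genes (0.43, percentile 99.99, Itgb8 3.25-fold) were higher. Hypothalamic neuropeptide genes were lower (-0.85, percentile 0), with Hcrt at 0.0696-fold, Oxt at 0.101-fold and Pmch at 0.113-fold. Oxidative phosphorylation (-0.62, percentile 0) and ribosomal protein genes (-0.76, percentile 0) were lower, and extracellular matrix genes had a median of -0.01 (percentile 61.6). With the length and GC trend removed, the medians were 0.20 for MAPK, 0.16 for PI3K-Akt, -0.21 for oxidative phosphorylation, -0.50 for ribosomal proteins and -0.37 for neuropeptides, and 1.00 for immediate early genes. The testis gene Smcp had 5.50 CPM in wild type and no count in the library labelled Csa-/-, and Tnp2 had 16.3 against 0.132 CPM. Of 12507 genes, 2625 differed beyond 1.5-fold, 1377 higher and 1248 lower. The balance turned when scaled by library totals alone, with 1200 higher and 1426 lower, and with the length and GC trend removed, with 550 and 621.

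**Figure D2:**
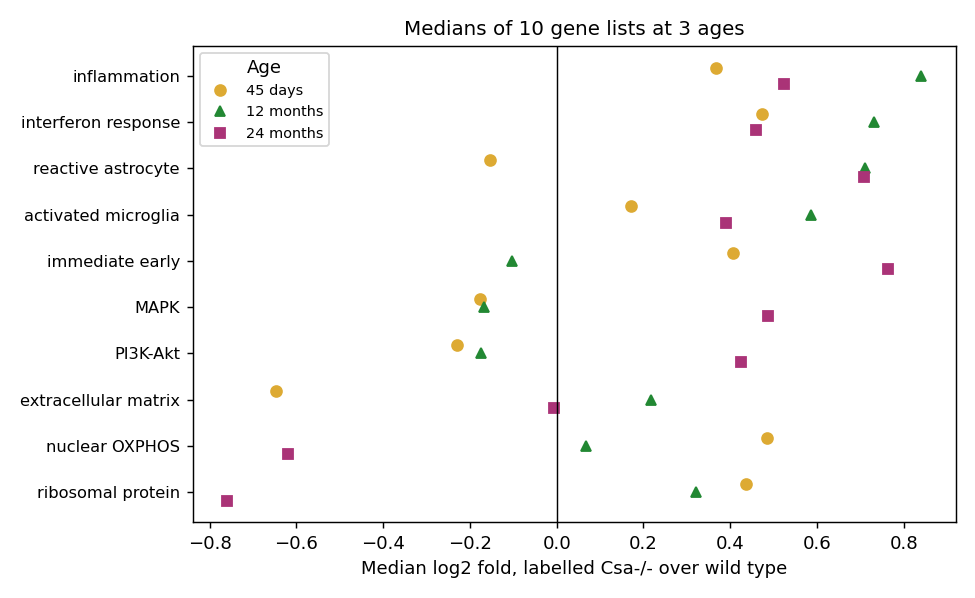
Median log2 fold of the library labelled Csa-/- over wild type for 10 gene lists fixed in advance, with 1 point per list and age (circles 45 days, triangles 12 months, squares 24 months). Inflammation and interferon-response medians were above 0 at the 3 ages (0.37 to 0.84), while extracellular matrix, ribosomal protein, MAPK and PI3K-Akt medians changed sign between ages.

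The genotype differences at the 3 ages had no positive correlation across genes, although more genes than in independent lists were higher at both 45 days and 12 months. For Itgb8, an integrin gene, the fold was 0.211 at 45 days and 3.25 at 24 months, and for Pomc, a pituitary hormone gene, it was 71.9 at 12 months and 0.0992 at 24 months. Over 12175 genes, Pearson's correlation across genes of the log2 genotype differences was -0.04 between 45 days and 12 months, -0.10 between 45 days and 24 months, and -0.41 between 12 and 24 months. Genes are not independent replicates. The same sign was found in 44.3%, 47.1% and 31.4% of genes. Opposite calls numbered 270 between 12 and 24 months, where independent lists would give 65.2, while 19 genes were higher at both ages (42.6 for independent lists) and 5 lower (24.4). Between 45 days and 12 months, 63 genes were higher at both ages (29.6 for independent lists), 9 were lower (13.5) and 62 were opposite (40.02). Between 45 days and 24 months, 40 were higher at both (98.7), 37 lower (61.7) and 274 opposite (157). The difference of the genotype effect between ages was not tested, since it is the only residual of a design with 1 library per group. Libraries also differed in their trend with gene length and GC content, with an R-squared of 0.167 to 0.390 over each library's deviations in log2 expression.

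**Figure D3:**
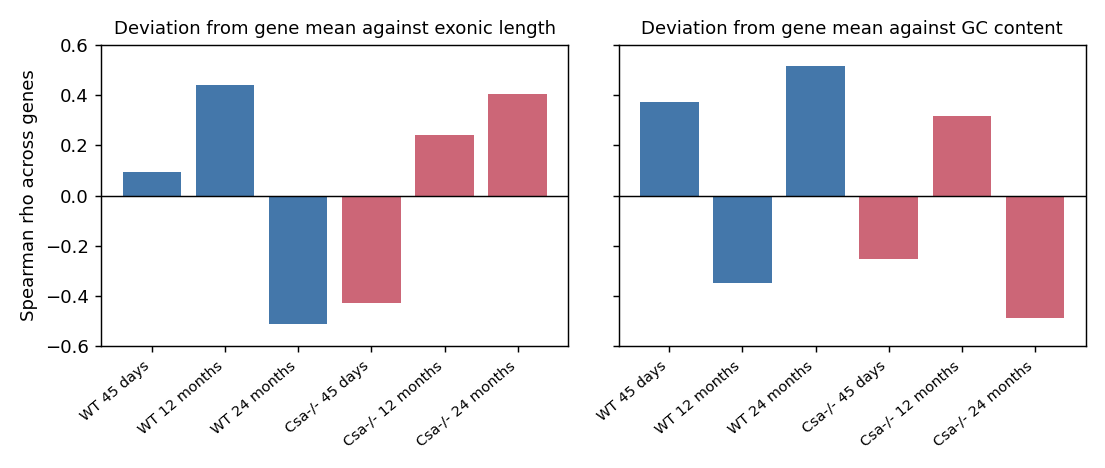
Spearman's rho across 12001 genes between the deviation of log2 expression from the gene's mean over the 6 libraries and exonic length (left) or GC content (right), with 1 bar per library and wild type and labelled Csa-/- in separate colours. For length, rho was -0.51 in wild type and 0.40 in the library labelled Csa-/- at 24 months, and for GC content 0.52 and -0.49.

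Between 45 days and 12 months, Abca8a, Egr2, C4b and Gpnmb rose across both genotypes, and Alb and S100a8 fell. Abca8a encodes a lipid transporter (log2 fold change 2.15 ± 0.39, SE, 2 libraries per age, edgeR adjusted p = 0.00247), and Egr2 is an immediate early gene (2.07 ± 0.45, adjusted p = 0.0299). C4b, a complement gene, went from 18.9 to 38.8 CPM in wild type and from 18.6 to 137 CPM in the libraries labelled Csa-/- (1.93 ± 0.40, adjusted p = 0.0170). Gpnmb rose by 2.25 ± 0.49 (adjusted p = 0.0299). Alb, which encodes albumin (-3.29 ± 0.61, adjusted p = 0.00247), and the neutrophil gene S100a8 (-3.44 ± 0.71, adjusted p = 0.0161) fell. Alb fell together with other liver transcripts, such as Serpina3k (5.04 to 0.160 CPM in wild type), a gene named after its values were seen. Ercc8 did not pass (-0.17 ± 0.39). All 10 genes called, 6 higher and 4 lower, moved the same way in both genotypes. The test favours such genes, since disagreement between genotypes is its residual. An unadjusted p under 0.05 was found for 402 genes. Without wild type at 45 days, 9 genes passed, and the adjusted p was 0.368 for Abca8a, 0.491 for Egr2, 0.371 for Alb and 0.120 for Gpnmb. Leaving out wild type at 12 months gave 9, with 0.278 for Abca8a, 1 for Egr2, Alb and S100a8, 0.109 for C4b and 0.771 for Gpnmb. Without the library labelled Csa-/- at 45 days, 3 passed, with 0.393 for Abca8a, 0.863 for Egr2, and 1 for C4b, S100a8 and Gpnmb. Without the one at 12 months, 2 passed, with 0.245 for Abca8a, 0.146 for Egr2, 1 for C4b, 0.958 for S100a8 and 0.706 for Gpnmb. Without either 24-month library 25 passed, 12 higher and 13 lower, and all 3 and 2 that passed without a library labelled Csa-/- at 45 days or 12 months were lower. No gene passed in edgeR with the length and GC trend removed (434 at an unadjusted p under 0.05). Abca8a then had 2.15 ± 0.29 (adjusted p = 0.0516), C4b 1.87 ± 0.32 (0.203), Egr2 2.17 ± 0.42 (0.290), Alb -3.08 ± 0.85 (1) and S100a8 -2.85 ± 0.82 (1), and the adjusted p of Gpnmb was 0.203. The folds of Abca8a, C4b, Gpnmb and Egr2 stayed near those before it, with the same fall in prior degrees of freedom. DESeq2 without that step called 8 genes and limma-voom 6. In DESeq2 the adjusted p was 1 for Alb and 0.265 for S100a8, and in limma-voom 0.137 for Egr2, 0.366 for S100a8 and 0.288 for Gpnmb.

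Immediate early genes were higher and myelin genes lower at 12 months than at 45 days, and markers of other regions and tissues moved as well. Of 20 immediate early genes, 19 were higher (median 0.71, camera adjusted p = 9.74e-15, adjusted p = 0.454 with an estimated correlation), and 8 passed when adjusted over the list alone. Of 20 genes of oligodendrocytes and myelin, 19 were lower (median -0.55, 8.87e-09, adjusted p = 0.454 with an estimated correlation), and 5 passed when adjusted over the list alone. None of the myelin genes passed in edgeR over all genes tested, with 8 at an unadjusted p under 0.05 and none passing in DESeq2 or limma-voom. Oxidative phosphorylation genes (29 of 31 lower, median -0.49, 1.98e-06, adjusted p = 0.581 with an estimated correlation) and ribosomal protein genes (32 of 33 lower, -0.37, 4e-05, adjusted p = 0.627 with an estimated correlation) were called lower. Their medians were -0.17 and -0.14 with the length and GC trend removed (camera adjusted p = 0.00204 and 0.0457). PI3K-Akt genes (34 of 43 higher, median 0.24, camera adjusted p = 0.00276, adjusted p = 0.627 with an estimated correlation) and MAPK genes (35 of 43 higher, 0.18, 0.0123, adjusted p = 0.654 with an estimated correlation) were called higher, and neither was called with that trend removed. Extracellular matrix genes were not called (22 of 47 higher, median -0.03, 0.288). Markers of skeletal muscle (7 of 7 lower, median -1.29, camera adjusted p = 2.2e-06) and cerebellum (15 of 16 lower, -0.49, 4.14e-05) were called lower, and those of striatum (14 of 15 higher, 0.41, 0.000229) and olfactory bulb (13 of 15 higher, 0.37, 8.50e-05) higher (all with adjusted p = 0.454 with an estimated correlation). Lymphocyte and neutrophil markers, S100a8 among them, were called lower (5 of 6, median -2.56, 7.96e-06, adjusted p = 0.454 with an estimated correlation). Pituitary markers were called higher too (11 of 12, 1.07, 0.00496, adjusted p = 0.654 with an estimated correlation). Of 41 lists, camera called 24. With an estimated correlation it called none (1 at an unadjusted p under 0.05), and fry called none (1 at an unadjusted p under 0.05).

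In wild type, immediate early genes stood higher at 12 months than at 45 days (median 1.07, percentile 100), with Egr2 at 5.61-fold, Nr4a1 at 3.58-fold and Egr1 at 3.42-fold. Myelin genes were lower (-0.77, percentile 0), 15 of 20 beyond 1.5-fold, with Cldn11 at 0.348-fold and Mal at 0.448-fold. Extracellular matrix genes were lower (-0.45, percentile 0), with the collagen genes Col1a1 at 0.258-fold and Col1a2 at 0.317-fold. Abca8a was 4.89-fold higher and Alb stood at 0.0149-fold. Cerebellum markers were lower (-0.69, percentile 0) and striatum markers higher (0.53, percentile 100). Once the length and GC trend was removed, the medians were 1.13 for immediate early genes, -0.67 for myelin and -0.38 for extracellular matrix. Ercc8 stood at 0.835-fold. Of 12301 genes, 671 differed beyond 1.5-fold, 264 higher and 407 lower. Scaled by library totals alone, the split was 190 higher and 539 lower.

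In the libraries labelled Csa-/-, glial genes stood higher at 12 months than at 45 days. Reactive astrocyte genes had a median of 0.88 (percentile 100), with Lcn2 at 14.4-fold and Gfap at 2.16-fold. Activated microglia genes had a median of 0.65 (percentile 100), with Itgax at 12.2-fold, Gpnmb at 5.80-fold and Clec7a at 4.70-fold, and complement genes one of 0.55 (percentile 99.8), with C4b at 7.36-fold and C3 at 7.02-fold. Immediate early genes were higher (0.60, percentile 100, Egr2 2.92-fold and Arc 2.89-fold). Myelin genes were lower (-0.48, percentile 0.01), with Opalin at 0.282-fold and Mog at 0.365-fold. Oxidative phosphorylation genes were lower (-0.71, percentile 0, Cox7a2 0.317-fold), with a median of -0.22 once the length and GC trend was removed. The homeobox gene Hoxb8 had 8.79 CPM at 12 months and no count at 45 days. Ercc8 stood at 0.942-fold. Of 12563 genes, 1793 differed beyond 1.5-fold, 784 higher and 1009 lower.

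Between 45 days and 24 months, several microglial genes and the complement gene C4b rose across both genotypes, and Alb and Col1a1 fell. Gpnmb rose from 0.665 to 5.84 CPM in wild type and from 1.41 to 29.0 CPM in the libraries labelled Csa-/- (log2 fold change 3.79 ± 0.50, SE, 2 libraries per age, edgeR adjusted p = 2.35e-07). C4b rose from 18.9 to 80.9 CPM and from 18.6 to 183 CPM (2.62 ± 0.40, adjusted p = 2.44e-05). The microglial genes Cst7 (3.19 ± 0.70, adjusted p = 0.0192), Itgax (2.89 ± 0.62, adjusted p = 0.0116) and Clec7a (2.29 ± 0.52, adjusted p = 0.0256) rose too. So did Abca8a (1.96 ± 0.39, adjusted p = 0.00508) and Fmo2 (2.16 ± 0.50, adjusted p = 0.0269). The olfactory gene Cdhr1 rose from 6.94 to 15.3 CPM in wild type and from 3.89 to 35.4 CPM in the libraries labelled Csa-/- (adjusted p = 0.00415). Omp, also olfactory (2.18 ± 0.53, adjusted p = 0.0467), Frmd7 (2.26 ± 0.46, adjusted p = 0.00576) and the pituitary hormone gene Cga (1.99 ± 0.46, adjusted p = 0.0298) rose as well. Alb (-4.66 ± 0.59, adjusted p = 2.35e-07) and the collagen gene Col1a1 (-1.63 ± 0.39, adjusted p = 0.0459) fell. Alb moved with other liver transcripts, since 18 of 28 liver markers, chosen after their values were seen, were higher in wild type at 45 days than at 24 months. Ercc8 did not pass (-0.09 ± 0.39). The test called 29 genes, 20 higher and 9 lower, and 378 had an unadjusted p under 0.05. Of the 29, 28 moved in the same direction in both genotypes, which the test favours.

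Among the named genes, only the call of Gpnmb held in the comparison of 24 months with 45 days whichever library was left out. The 12-month libraries are not part of this contrast. Their omission acts through the genotype term, the estimated spread and fewer residual degrees of freedom, so a call lost there does not rest on a 12-month level. Without the library labelled Csa-/- at 45 days, 13 genes passed, 4 higher and 9 lower, and the adjusted p was 0.510 for C4b, 0.532 for Frmd7, 0.364 for Abca8a, 0.730 for Col1a1, 0.933 for Cst7 and 1 for Cdhr1, Fmo2, Cga, Itgax, Clec7a and Omp. Omitting wild type at 45 days gave 19, with 0.151 for Frmd7, 0.312 for Fmo2, 0.671 for Abca8a, 0.185 for Alb, 0.986 for Col1a1 and 0.259 for Cst7. Without wild type at 12 months, 13 passed, with 0.0617 for Frmd7, 0.0974 for Cdhr1, 0.148 for Fmo2, 0.165 for Col1a1, 0.0776 for Cst7, 0.0672 for Clec7a and 0.149 for Omp. Without the 12-month library labelled Csa-/-, 14 passed, with 0.0558 for Cdhr1, 0.102 for Fmo2, 0.119 for Col1a1, 0.0860 for Cst7, 0.0538 for Clec7a and 0.109 for Omp. Omitting wild type at 24 months gave 62, 31 higher and 31 lower, with 0.787 for Cga, 0.239 for Cst7 and 0.0645 for Clec7a. Without the 24-month library labelled Csa-/-, 63 passed, with 0.520 for Frmd7, 0.533 for Cdhr1, 1 for Fmo2, 0.289 for Col1a1 and 0.297 for Omp. Correcting the length and GC trend left 6 genes, among them Gpnmb (adjusted p = 0.00335), C4b (0.0123) and Abca8a (0.0253). Of the other named genes, Col1a1 had 0.0822 (-1.67 ± 0.28), and none of the rest passed, with values up to 1. Their folds stayed near those before it, as with Cst7 (3.47 ± 0.67), Fmo2 (2.19 ± 0.45) and Clec7a (2.43 ± 0.60), with the same fall in prior degrees of freedom. In DESeq2 the adjusted p was 0.0982 for Fmo2, Cst7 and Itgax, 0.0962 for Clec7a, 0.125 for Omp, 0.706 for Alb and 1 for Cga. In limma-voom it was 0.0834 for Fmo2, 0.0509 for Cga and 0.101 for Cst7. With a mean of at least 5 CPM it was 0.0650 for Col1a1.

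Interferon-response, inflammation, activated microglia and complement genes were higher at 24 months than at 45 days, and myelin genes and markers of lymphocytes and neutrophils lower. Of 26 interferon-response genes, 25 were higher (median 0.77, camera adjusted p = 9.41e-22, adjusted p = 0.271 with an estimated correlation), and 7 passed when adjusted over the list alone. None of the 26 passed in edgeR over all genes tested, with 12 at an unadjusted p under 0.05, 1 passing in DESeq2 and none in limma-voom. Of 31 inflammation genes, 28 were higher (0.74, 5.03e-18, adjusted p = 0.271 with an estimated correlation), and none passed in edgeR over all genes tested or adjusted over the list alone, with 12 at an unadjusted p under 0.05 and none passing in DESeq2 or limma-voom. Activated microglia genes (15 of 16 higher, 0.56, 8.02e-17, adjusted p = 0.286 with an estimated correlation) had 4 genes that passed, and 6 adjusted over the list alone. Complement genes (9 of 12 higher, 0.77, 5.08e-08, adjusted p = 0.286 with an estimated correlation) had 1 and 4. Reactive astrocyte genes were called higher (18 of 19, 0.57, 1.22e-09, adjusted p = 0.404 with an estimated correlation). Myelin genes were lower (18 of 20, median -0.58, 1.57e-12, adjusted p = 0.282 with an estimated correlation), and 7 passed when adjusted over the list alone. Olfactory bulb markers (14 of 15, 0.64, 3.57e-11, adjusted p = 0.271 with an estimated correlation) and pituitary markers (12 of 12, 1.59, 1.49e-11, adjusted p = 0.408 with an estimated correlation) were called higher. Lymphocyte and neutrophil markers were called lower (5 of 6, median -1.39, camera adjusted p = 0.000177, adjusted p = 0.455 with an estimated correlation). Markers of skeletal muscle (6 of 7, median -1.16, 3.88e-07, adjusted p = 0.369 with an estimated correlation) and cerebellum (15 of 16, -0.35, 7.84e-05, adjusted p = 0.271 with an estimated correlation) were called lower. Extracellular matrix (17 of 47 higher, median -0.06, 0.0528), PI3K-Akt (25 of 43, 0.04, 0.513) and MAPK genes (29 of 43, 0.08, 0.734) were not called. Of 41 lists, camera called 19. With an estimated correlation it called none (6 at an unadjusted p under 0.05), and fry called none (5 at an unadjusted p under 0.05).

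In wild type, interferon-response genes stood higher at 24 months than at 45 days (median 0.84, percentile 100), with Rtp4 at 3.88-fold and Bst2 at 3.27-fold. Inflammation genes were higher (0.75, percentile 100), with the antigen-presentation genes H2-Aa at 2.89-fold and H2-K1 at 2.41-fold. Complement genes (0.67, percentile 100, C4b 4.28-fold and C1qa 2.63-fold) and activated microglia genes (0.50, percentile 100, Gpnmb 8.78-fold and Lyz2 2.49-fold) were higher. Myelin genes (-0.47, percentile 0.01, Cldn11 0.338-fold) and oligodendrocyte precursor markers (-0.46, percentile 0.04, Gpr17 0.332-fold) were lower. Extracellular matrix genes were lower (-0.40, percentile 0, Col3a1 0.233-fold). With the length and GC trend removed, the medians were 0.77 for interferon response, 0.49 for inflammation, -0.37 for myelin and -0.31 for extracellular matrix. Ercc8 stood at 0.917-fold. Of 12442 genes, 876 differed beyond 1.5-fold, 414 higher and 462 lower. Scaled by library totals alone, the split was 532 higher and 371 lower.

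In the libraries labelled Csa-/-, reactive astrocyte genes stood higher at 24 months than at 45 days (median 1.08, percentile 100), with Osmr at 2.83-fold and Gfap at 2.35-fold. Gpnmb was 20.6-fold higher (95% counting interval 13.4 to 33.4), Itgax 16.8-fold and Clec7a 7.57-fold, in an activated microglia list with a median of 0.72 (percentile 100). Complement genes (0.72, percentile 100, C4b 9.86-fold and C3 7.88-fold) and interferon-response genes (0.78, percentile 100, Lgals3bp 4.45-fold and Ifit1 3.36-fold) were higher, as were inflammation genes (0.74, percentile 100) and immediate early genes (0.84, percentile 100). Myelin genes were lower (-0.82, percentile 0), with Opalin at 0.304-fold and Mog at 0.327-fold. MAPK genes had a median of 0.31 (percentile 99.7) and extracellular matrix genes one of 0.21 (percentile 99.7), in which Tnr stood at 3.05-fold and Col1a1 at 0.293-fold. Oxidative phosphorylation (-0.77, percentile 0) and ribosomal protein genes (-0.80, percentile 0) were lower, with medians of -0.17 and -0.36 once the length and GC trend was removed. Ercc8 stood at 0.967-fold. Of 12517 genes, 2025 differed beyond 1.5-fold, 866 higher and 1159 lower.

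Between 12 and 24 months, interferon-response, inflammation and activated microglia genes were higher as lists across both genotypes, and no single gene of them passed. Interferon-response genes (25 of 26 higher, median 0.74, camera adjusted p = 1.49e-14, adjusted p = 0.510 with an estimated correlation) had 8 genes at an unadjusted p under 0.05 in edgeR. Inflammation genes (26 of 31 higher, 0.49, 1.46e-11, adjusted p = 0.533 with an estimated correlation) had 4. Activated microglia genes (16 of 16 higher, 0.55, 5.79e-11, adjusted p = 0.764 with an estimated correlation) also had 4, and 1 of them passed when adjusted over the list alone. None of these genes passed in DESeq2 or limma-voom. Immediate early genes were called lower (19 of 20, median -0.22, 7.47e-05, adjusted p = 0.764 with an estimated correlation) and oxidative phosphorylation genes higher (30 of 31, 0.31, 0.000224, adjusted p = 0.764 with an estimated correlation). With the length and GC trend removed the median of oxidative phosphorylation was 0.16 (camera adjusted p = 0.0178). PI3K-Akt (35 of 43 lower, median -0.16, 0.00892, adjusted p = 0.764 with an estimated correlation) and MAPK genes (32 of 43 lower, -0.12, 0.0164, adjusted p = 0.764 with an estimated correlation) were called lower, and neither was called with the length and GC trend removed. Pituitary markers were called higher (9 of 12, median 0.33, 8.62e-05, adjusted p = 0.764 with an estimated correlation) and striatum markers lower (14 of 15, -0.29, 0.00155, adjusted p = 0.764 with an estimated correlation). The edgeR test called 1 gene, with 163 at an unadjusted p under 0.05. It was the airway and olfactory secretion gene Bpifa1 (3.96 ± 0.77, SE, 2 libraries per age, adjusted p = 0.0297), named after its value was seen. DESeq2 and limma-voom called none (81 and 136 genes at an unadjusted p under 0.05). Without wild type at 12 months edgeR called none (217 at an unadjusted p under 0.05). Without wild type at 45 days or 24 months it called 2 and 14 (3 of the 14 higher), and without the libraries labelled Csa-/- at 45 days, 12 months and 24 months 2, 5 and 26. Ercc8 did not pass (0.09 ± 0.39). Of 41 lists, camera called 16. With an estimated correlation it called none (2 at an unadjusted p under 0.05), and fry called none (1 at an unadjusted p under 0.05).

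In wild type, immediate early genes stood lower at 24 than at 12 months (median -0.87, percentile 0), with Egr2 at 0.292-fold. Activated microglia genes (0.88, percentile 100, Lyz2 3.21-fold), complement genes (0.80, percentile 100, C1qb 2.48-fold), interferon-response genes (0.71, percentile 99.98, Bst2 5.63-fold) and inflammation genes (0.63, percentile 99.96, Cd74 3.43-fold) were higher. Pituitary markers were higher (2.84, percentile 100), with Pomc at 85.0-fold and Gh at 9.93-fold. MAPK (-0.48, percentile 0.02) and PI3K-Akt genes (-0.45, percentile 0.03) were lower, and ribosomal protein (0.93, percentile 100) and oxidative phosphorylation genes (0.66, percentile 100) higher. Medians without the length and GC trend were -0.24 for MAPK, -0.13 for PI3K-Akt, 0.39 for ribosomal proteins, 0.32 for oxidative phosphorylation and -0.97 for immediate early genes. Ercc8 stood at 1.10-fold. Of 12436 genes, 2284 differed beyond 1.5-fold, 1072 higher and 1212 lower. Scaled by library totals alone, the split was 1449 higher and 765 lower, and the median of all genes was 0.14 against 0.03 in the scaling used.

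In the libraries labelled Csa-/-, interferon-response genes stood higher at 24 than at 12 months (median 0.60, percentile 100), 6 of them beyond 1.5-fold and none lower. Inflammation genes had a median of 0.42 (percentile 99.99) and GABAergic genes one of 0.39 (percentile 100). Gpnmb was 3.55-fold higher, Fmo2 3.22-fold, Osmr 2.14-fold and Sgk1 1.97-fold. Lcn2 stood at 0.255-fold, Pomc at 0.117-fold and Hoxb8 at 0.0451-fold, from 8.79 to 0.397 CPM. Medians without the length and GC trend were 0.42 for interferon response, 0.26 for inflammation and 0.24 for GABAergic genes. Ercc8 stood at 1.03-fold. Of 12435 genes, 647 differed beyond 1.5-fold, 213 higher and 434 lower.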

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

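The test of testis transcripts was chosen only after that result was seen. The test by splits of libraries was written first, as were those of gene length, GC content and depth, although these corrections were added after the data were seen. Flags mark a run far from the other runs of its library, or a genotype difference of opposite direction at different ages.

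In 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, the edgeR test called as many as 30 genes. The highest other split called 24. With 10 splits no share under 0.05 could be reached.

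Testis transcripts were higher in wild type at 24 months than in the library labelled Csa-/-. Of testis markers not among the calls, 83.3% were higher there (25 of 30), against 35.1% of other genes and 23.7% of genes with similarly low counts. RNA or reads from testis would give this, although 3 of the 30 were lower there. The summed level of these 30 markers was 265 CPM in that library against 157 to 199 CPM in the others. Odf2 alone took 119 CPM there and 79.1 to 114 CPM in the others, so the sum is a weak measure. At low counts the other wild-type libraries held testis transcripts too. Of the called genes, Akap4 had 19, 8 and 147 counts in wild type at 45 days, 12 and 24 months. It had none in the libraries labelled Csa-/-. Prm2 had 31, 33 and 233 counts against 0, 3 and 4. Of the markers, 13 had a median of at least 1 CPM, so brain cells may express part of them. The lower testis genes between genotypes therefore cannot be read as an effect of Ercc8.

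Genotype differences at 12 and 24 months went in opposite directions across genes. With every library thinned to the smallest total, the correlation across genes was -0.39, which cannot decide on depth. The differences at these ages share no library, so counting noise alone would only weaken their correlation. The genes had a mean of at least 5 CPM, so thinning could change their folds little. It cannot undo a bias that goes with depth, so such a bias is left open. Gene length and GC trends cannot be told apart from a change of the genotype effect with age. Removing the trends brought the correlation from -0.40 to -0.246. That lay between the bounds written before this test, but barely short of the lower one, -0.25. A change of the effect with age is untested, because each group had 1 library, and it may equally be a difference between those libraries.

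Run 4 of the wild-type library at 24 months stood apart from the other 4 runs, with a total of 2821708 counts and 17627 genes detected. These were 2 of 18 combinations of a group of runs and a quantity, where chance flags about 1 in 20. Both flags mark the same run, and a lower total lowers the genes detected, so they are not independent.

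Of 55 genes with the largest folds, 14 had a genotype difference beyond 1.5-fold in opposite directions at 2 of the ages. The difference between ages was not tested. Its size on the log2 scale was 9.50 for Pomc, 6.17 for Baiap2l1, 4.87 for Slc6a2, 4.39 for Ccl28, 3.96 for Slc6a5, 3.95 for Itgb8, 3.83 for Ndufb4 and 3.78 for Eps8l1. It was 3.38 for Cartpt, 3.34 for Lmbrd2, 2.77 for Svbp and 2.41 for Gpr34, and among small or noncoding RNA genes 5.76 for Snord15b and 5.04 for Mir6236.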

How the results depend on the processing

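The removal of length and GC trends, the thinning of libraries and the omission of run numbers were chosen only after the data were seen. No call of a named gene changed direction. Ercc8 between genotypes, not called, went from 0.12 to -0.03 with length and GC trends removed. The majority direction of single-library calls turned with library totals, without a level minimum, and with those trends removed, for the genotypes at 24 months and in wild type for 24 months against 45 days and against 12 months. With 30 columns, with or without the replicate block, it turned in the first and last of these. With the block it also turned for the genotypes at 12 months, with 3952 higher and 3964 lower. Of named genes in tested comparisons, 374 values stayed on their side of the threshold and 115 lost the call. The call of Gpnmb between 45 days and 24 months held in every setting (log2 fold change 3.27 to 4.22). In single-library comparisons 6678 values of named genes held within their counting interval and 782 moved, 637 of them with length and GC trends removed. The causes were not tested unless given. Depth limits genes of low level, whose floor was 0.0796 to 0.206 CPM.

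Counts of genes past the threshold are given in the order genotype, 12 months against 45 days, 24 months against 45 days, and 24 against 12 months, where edgeR gave 30, 10, 29 and 1. DESeq2 size factors, library totals and omission of the 10 genes with most counts kept all 4 within 1.5 times. Without a low-count filter 90 genes passed between genotypes and 3 between 12 and 24 months, with 21808 genes tested. At a mean of at least 5 CPM, 7, 6, 9 and 0 passed (52 at an unadjusted p under 0.05 in the last). DESeq2 called 12 between genotypes, 13 and 0. Limma-voom called 6 between 45 days and 12 months and 0 between 12 and 24 months. With length and GC trends removed edgeR called 11, 0, 6 and 0 (434 and 163 at an unadjusted p under 0.05 where none passed). Leaving out 1 library in turn gave 40 to 72, 2 to 25, 13 to 63 and 0 to 26 genes, with fewer samples and a lone library per age assumed to vary like the others.

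Columns taken as 30 replicates gave 3310, 4511, 2579 and 2079 genes, since the runs then stood for animals. With the replicate block they gave 2970, 4035, 2300 and 1681. Same-numbered runs deviated together weakly but regularly, so the numbers may mark something that these runs share, which was not tested. Of 75 same-numbered pairs, correlations of deviations ran from 0.0125 to 0.194 (median 0.0718, against -0.0271 for other numbers), and 24 of 30 runs correlated best with their own number.

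Lists called by camera numbered 20, 24, 19 and 16, and 0 in all 4 comparisons with an estimated correlation and 0 with fry. With length and GC trends removed, 17, 22, 18 and 11 of these were shared with the same direction.

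Single-library counts beyond 1.5-fold are given for the genotypes at 45 days, 12 and 24 months, then 12 months against 45 days, 24 months against 45 days and 24 against 12 months, each in wild type and then in libraries labelled Csa-/-. With length and GC trends removed they were 724, 516, 1171, 443, 783, 567, 1153, 1019 and 366. Of these 530, 359, 756, 310, 559, 426, 843, 652 and 242 were shared. The 30 columns gave 9151, 7653, 10641, 8002, 8911, 8605, 9825, 10093 and 8297 genes by test, and the replicate block 9370, 7916, 10959, 8263, 9100, 8941, 10051, 10327 and 8589. Without a level minimum 24 months against 45 days in wild type gave 1516. Genes with opposite genotype calls at 12 and 24 months numbered 270, and 99 with those trends removed. The 30 columns gave 4693 genes with opposite calls by test at these ages, and the replicate block 4843. No contrast of the genotype effect between ages was fitted. DESeq2, limma-voom and omission of a library were not run for single-library comparisons and for the difference between ages, which leave no residual.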

Other observations

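Transcripts of liver were present at low levels. Of 28 liver markers, 18 were higher in the wild-type library at 45 days than at 24 months, and Alb stood at 25.1 CPM at 45 days. These genes were chosen after their values were seen.

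The nuclear ribosomal RNA gene Rn45s took 0.105% to 0.977% of the counts of a library.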
